A study of Rattus norvegicus with 12 samples.

How the data were processed

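The series compared punched tissue labelled NTS from 6 alcoholic rats and 6 paired controls on 12 arrays with 2 colours; what the abbreviation stands for, and how the animals were treated, is not given in the sources used here. Per the labels, RNA was isolated, amplified and labelled indirectly, with the reference in Cy3 and the animal's RNA in Cy5 on every array. All arrays had one dye orientation, so a dye effect common to all arrays cancels in the difference between groups. The reference is no sample of either group, and its make-up is not given in the sources used here.

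The deposited value table held log2 ratios of 18144 features, with background correction, filters and normalization not given in the sources used here. The log base was read from the values: the largest size was 13.92, while 16-bit signals allow at most 11.09 in natural logs and 4.816 in log10. The deposited log2 ratios were not centred, with array medians from 0.35 to 1.85 (mean 0.87 in alcoholic and 0.92 in control arrays). The direction stayed unstated and was taken from the dyes as likely. Exact zeros numbered 484 to 726 per array, against 14 to 55 values at a neighbouring hundredth, and were treated as missing; that choice was made after the values were seen. Signals over background were not used here, and neither were intensities of single channels.

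Features were named through an older platform annotation, so symbols can be out of date. It gave 1 gene symbol for 10118 features, several for 1092 and none for 6934. No table of synonyms was used, so list genes were matched by their symbol as written, and 481 of 1232 were measured. Neighbouring spots of one accession, 5597 in number, correlated with r of 0.923 to 0.954 per array. Features more than 3 numbers apart that shared an accession, 12 pairs in all, correlated with r = 0.95 in their mean log2 ratio. For 583 pairs of different accessions of one gene that coefficient was 0.06, so levels of different clones of a gene disagreed. Over 414 genes with at least 2 accession groups, the coefficient of the differences between groups was -0.04 between the first and the second, against 0.03 after shuffling, and profiles over the arrays had a median r of 0.09 against 0.04 for random features. That median was only 0.27 for separated features that share an accession (11 profiles), and no gene was called. The low coefficients of differences and profiles therefore cannot show whether clones measure the same gene. Levels say more: random features had a coefficient of 0.004, so clones under 1 symbol agreed hardly more than random ones. Values of genes averaged over several clones, and of lists, carry that doubt. Genes read from 1 clone are not free of it, since features that shared an accession did agree in level and no symbol was checked.

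Each array was centred on its median, and features with the same single symbol were averaged. In all, 11835 genes or unnamed features with both values in at least 4 pairs were tested, 4497 of them with 1 symbol. The other 7338, with several symbols or none, are the unnamed features and were not averaged. Counts of genes include them unless a single symbol is stated. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the animal pair as a fixed block and Benjamini-Hochberg adjustment at 0.05. Intervals are at 95%. The fit's 6 animals per group, not features, are the replicates. The block was taken from the labels, which state the pairs. Deviations of the arrays of a pair from their group means correlated across genes with r of 0.26, 0.34, 0.01, 0.43, 0.20 and 0.09 for pairs 1 to 6. The mean was 0.22 for arrays of one pair and -0.04 for arrays of different pairs. Only 3 of the 6 alcoholic arrays correlated best with the control of their own pair. Those of pairs 3, 5 and 6 did so with the controls of pairs 1, 6 and 5. Whether arrays were exchanged between pairs was not tested.

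Gene lists, 34 in number, were fixed before the data were examined, together with the groups, the main test and most alternatives; 481 genes held 504 places in them, so some genes stood in more than 1 list. Lists with at least 5 members were tested two-sided with limma's cameraPR at a preset correlation of 0.01 on the moderated statistics of the same fit, since camera itself cannot take missing values. Camera with an estimated correlation, and fry, used the 11011 genes complete on all arrays. The rule for named genes took up to 12 called genes in each direction, filled to 8 with the smallest unadjusted p where fewer were called. It added for each list the members called, at most 4, or the 2 with the smallest p where none was called, and 10 genes named in advance where measured (Th, Dbh, Npy, Agt, Agtr1a, Gad1, Fos, Gfap, Aldh2 and Cat).

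The test was tested on simulated data with the real genes' means, pair effects and residual spread, 50 genes being changed at each of 4 sizes among 11011. It called 3 at 1.41-fold, 41 at 2-fold, 49 at 2.83-fold and 49 at 4-fold, with 8 false calls, and of the unchanged genes 5.23% had an unadjusted p under 0.05. The list of cytosolic ribosomal proteins, the largest with 37 genes, was called when shifted by 0.3, and no other list was. Errors were drawn independently for each gene, so this does not show how smaller lists or correlated genes fare. The genes were all changed at once, so it does not show either how often a lone changed gene is called.

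Alternatives set before the data were examined were no centring, quantile normalization, a common spread of arrays, no pair block, the pair as a random effect, other filters on missing and low values, single features, a variance trend with robust fitting, array weights, other thresholds and leaving out each pair. Chosen after seeing the data were exact zeros kept, loess of each array on the mean log2 ratio, a further loess along the feature number with a span of 0.02, and an estimated correlation for lists of single features. Group labels were also exchanged within pairs in all 32 ways, and 100 of the 462 splits of the 12 arrays were drawn for the fit without the block, which also took the 32 ways. Figures were drawn with matplotlib 3.10.9.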

Results

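RNA was measured in tissue punches that the labels call NTS, from rats described as alcoholic and from their paired controls. There were 6 animals in each group, joined by the labels into 6 animal pairs, and each animal had 1 array. On every array the animal's own RNA carried the red dye Cy5 and a reference RNA the green dye Cy3. The deposited value of each of the 18144 array features was a log2 ratio, taken here as sample over reference. That direction is likely from the dyes but is not stated with the values, and every sign below turns if it runs the other way. Array medians lay between 0.35 and 1.85 before each array was centred on its own median. The number of arrays limits the precision of every value below, and each of the 6 animals per group counted as 1 replicate.

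The question the pairing addresses is which genes differ in this tissue between alcoholic animals and their controls. No gene was called as higher or lower. Of the 11835 genes or unnamed features tested, 0 passed an adjusted p of 0.05 in limma's test with the animal pair as a block. The smallest adjusted p was 0.999. Of those tested, 4497 had 1 gene symbol, and counts of genes below include the unnamed features. Among the 8 genes with a single symbol and the smallest p in each direction, Scrt1, a zinc finger transcription factor of neurons, had the widest positive difference, 2.48 on the log2 scale, and Lyl1, a basic helix-loop-helix transcription factor, the widest negative one, -2.09; an unnamed feature stood at -2.53. Npy, the peptide transmitter neuropeptide Y, stood 0.32 above control, and Cat, the peroxide-degrading enzyme catalase, 0.21. Aldh2, the mitochondrial enzyme that oxidizes acetaldehyde, differed by -0.01.

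By limma, 290 genes had an unadjusted p under 0.05, 155 higher and 135 lower in alcoholic animals, where a uniform spread of p gives 592 and the other ways to assign the labels within pairs had a median of 446. Of the 11011 genes measured in all 6 pairs, 177 went one way in every pair, 88 higher and 89 lower. That is 1.61%, against the 3.125% that even odds in each pair give. The other ways to assign the labels within pairs gave 177 to 641 such genes, with a median of 319, so chance cannot be excluded. Without pair 3 the count at unadjusted p rose to 438, and it was 142 in the fit without the pair block; neither fit called a gene at an adjusted p of 0.05. The values without centring, with exact zeros still treated as missing, called 4 features, among them Lyl1 and Scrt1.

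The intervals show which sizes of change these arrays leave open. The median standard error of a log2 difference was 0.16, with quartiles of 0.13 and 0.22. For 10265 genes, or 86.7% of those tested, the 95% interval lay within a 2-fold change either way, and for 66.0% within 1.5-fold. In simulated data of the same design, 6% of genes changed 1.41-fold were called, 82% of those changed 2-fold and 98% of those changed 4-fold. The simulated genes were complete on all arrays and had independent errors, and 50 genes at each of 4 sizes were changed at once. The Benjamini-Hochberg cut is looser when many genes change. A 2-fold change in only a few genes would therefore be called less often. In limma's test 5.23% of the unchanged simulated genes had an unadjusted p under 0.05, against 2.45% of the real genes. These shares therefore need not hold for the real data.

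Among the genes with the smallest unadjusted p in the positive direction, Scrt1 stood at a log2 ratio of 4.39 ± 1.43 (SD, n = 5) in alcoholic and 1.99 ± 0.59 (SD, n = 6) in control animals. Its difference within pairs had a standard error of 0.46, and 5 of 5 measured pairs were higher. Hsd17b12, an enzyme of fatty acid elongation, differed by 1.67 (SE 0.29, 5 of 5 pairs higher). The transcription factor genes Erf, Zbtb7a and Hhex differed by 1.55, 1.17 and 0.96, with standard errors of 0.41, 0.27 and 0.24. Acsl1, which activates long-chain fatty acids, differed by 0.78 (SE 0.22) and was higher in 6 of 6 pairs, but by 0.04 on its single feature with the most measured pairs. On such single features Hhex differed by 0.42. With exact zeros kept as values, Zbtb7a differed by 0.43 and Hhex by 0.315. Timm44, of the mitochondrial protein import machinery, and Arhgef19 differed by 0.46 and 0.38, and by 0.59 and 0.64 on single features.

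On the negative side, Lyl1 had a difference of -2.09 (SE 0.53) and was lower in 5 of 5 measured pairs. Vapb, a membrane protein of the endoplasmic reticulum, differed by -1.27 (SE 0.42, 4 of 5 pairs lower). Fbxo16 differed by -0.93 (SE 0.14) in the 4 pairs that measured it. Syde1, Wapl, Pou2af3, Triqk and Selenos differed by -0.74, -0.72, -0.62, -0.47 and -0.38. Selenos, a selenoprotein of the endoplasmic reticulum, was lower in 6 of 6 pairs, and Wapl, which releases cohesin from chromatin, in 5 of 6. On single features Wapl differed by -0.04 and Syde1 by -1.38, and Syde1 by -2.23 with exact zeros kept and -0.49 without pair 5. Several of these genes, such as Scrt1, Lyl1 and Hsd17b12, lie where the mean log2 ratio exceeds 2; there 23.8% of values were missing and the median SD of a feature over the arrays was 1.19, against 0.34 for ratios from 0 to 2. With exact zeros kept as values, the differences of Scrt1 and Fbxo16 changed sign.

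**Figure D1:**
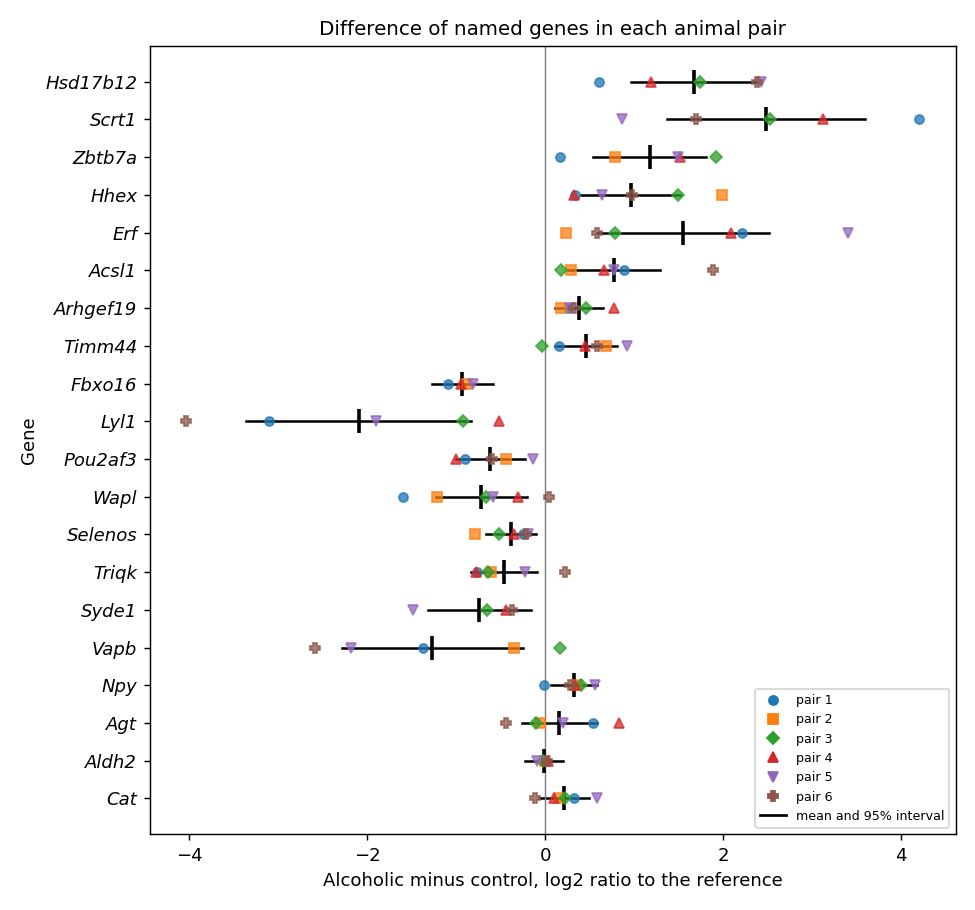
Each point is the alcoholic minus control difference of 1 animal pair (x axis, log2 ratio to the reference) for the genes on the y axis; the upright mark is the mean and the line its 95% interval from limma. Scrt1 averages 2.48 and Lyl1 -2.09, with points of single pairs spread widely, and no gene passes an adjusted p of 0.05.

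No tested list of transmitter or peptide signalling genes was called as shifted. Small shifts stay open, since measured members ranged only from 6 of 52 (neuropeptide receptors) to 19 of 47 (neuropeptides and hormones). Of 34 lists fixed before the data were examined, 31 had at least 5 members and were tested with limma's camera, and 0 passed an adjusted p of 0.05; the smallest was 0.968. An estimated correlation between genes and the fry test also called 0 lists. Sizes given for single members are loose, since leaving out 1 pair moved 55 of the 82 genes named here by over 1.5 times, and single features moved 29 of 77. Symbols are a further limit on genes and lists, since mean log2 ratios of different clones of 1 gene correlated at only 0.06. Of the 481 list genes measured, 0 passed when adjusted over the list alone, the smallest such value being 0.27 for Acsl1 in the lipid list. Among 19 neuropeptides and hormones, 11 were higher and 8 lower, with a list median of 0.06. Npy had the smallest p by limma, at 0.32 (95% interval 0.06 to 0.58, higher in 5 of 6 pairs) and at 0.19 on a single feature. Oxt, which encodes oxytocin, differed by 0.41 with an interval from -0.31 to 1.14, and by 0.09 without pair 3. The neuropeptide receptors had the lowest median of the tested lists, -0.10, with 4 of 6 lower; the bradykinin receptor gene Bdkrb2 differed by -0.33 and Calcrl by -0.21, or by -0.15 without pair 3 and -0.08 without pair 5.

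Among the glutamate signalling genes 6 of 9 were higher, with a median of 0.04. The AMPA receptor subunit gene Gria2 differed by -0.31 (95% interval -0.62 to 0.01, lower in 5 of 6 pairs) and the glutamate transporter gene Slc1a1 by -0.18 (-0.06 without pair 4). The catecholamine and serotonin list split 4 higher to 3 lower around a median of 0.00, with Gch1, which makes the cofactor of tyrosine hydroxylase, at -0.42 (SE 0.33, -0.10 without pair 6) and Adra1b at -0.21. Only 4 GABA and glycine genes were measured, too few for the test, among them Gabrd at 0.10 and Slc32a1 at -0.04. In the renin-angiotensin and blood pressure list 6 of 8 were higher, with a median of 0.04. Agt, the precursor of angiotensin, differed by 0.16 (95% interval -0.26 to 0.58; 0.03 without pair 4) and Gucy1a1 by -0.16. Potassium channel genes had a median of -0.02 (Kcnn3 0.21, Kcnc1 -0.11), sodium and calcium channel genes 0.02 (Cacna1g -0.21, Atp2a2 -0.71) and synaptic vesicle genes 0.02 (Vamp1 0.38, Snap23 0.08). Without pair 2, Atp2a2 differed by -0.28 and Vamp1 by 0.14, and with exact zeros kept by -0.14 and 0.03; without pair 6, Snap23 differed by 0.005. Th, Dbh, Agtr1a, Gad1, Fos and Gfap were not tested here, since 0 features carried any of these symbols, alone or among several.

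Ethanol metabolism and antioxidant genes showed 14 of 33 members higher and 19 lower, with a median of -0.01. The glutathione transferase gene Gsta2 had the smallest p of this list by limma, with a difference of 1.52 (SE 0.62, higher in 5 of 6 pairs) that came to 0.85 without pair 2. Lipid and cholesterol genes had 22 of 31 members higher and a median of 0.02, with Cpt2, of mitochondrial fatty acid oxidation, at -0.22. Oxidative phosphorylation genes had a median of 0.01 (Ndufa5 0.42, Atp5f1d -0.14) and genes of glycolysis and the tricarboxylic acid cycle -0.01 (Idh2 0.24, Ldha -0.24). The 39 cytosolic ribosomal protein genes had a median of -0.01, with Rpl11 at 1.86 (SE 0.88, 4 pairs; 0.46 with exact zeros kept, 3.0 without pair 4) and Rpl10 at -0.20. Proteasome and ubiquitin genes had a median of -0.01; the ubiquitin ligase gene Nedd4 differed by 0.49 and was higher in 6 of 6 pairs, but by 0.04 on a single feature, while Psmb1 differed by -0.16. The median was -0.03 for heat shock and endoplasmic reticulum stress genes (Hspe1 0.45, Ddit4 -0.14) and 0.00 for immediate early and clock genes (Sgk1 0.19, Klf2 -0.45). Hspe1 differed by 0.12 without pair 3, Ndufa5 by 0.22 and Ldha by -0.11 without pair 4, and Klf2 by -0.08 with exact zeros kept.

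Among kinase and cyclic nucleotide genes the median was -0.01, with the calcineurin subunit gene Ppp3ca at 0.25 and the adenylyl cyclase gene Adcy3 at -0.26. G protein genes had a median of 0.00 (Gnas -0.17, Arrb2 -0.16) and neurotrophin and growth factor genes 0.01 (Igfbp5 0.71, Igfbp2 0.29); Igfbp5 differed by 0.41 without pair 1 and by 0.15 on a single feature. In the list of TGF-beta and bone morphogenetic proteins 16 of 19 members were higher, but by small amounts with a median of 0.05 (Tgfb2 0.26, Bmp7 0.19). The camera p of this list was 0.128 before adjustment and 0.974 after it. Cytokine and inflammation genes had a median of 0.04 with 12 of 20 higher; Ifngr1, an interferon gamma receptor gene, differed by 2.16 with an interval from -0.76 to 5.09 (6.88 in pair 5, and a mean of 0.59 over the other 3 measured pairs), and Cxcr4 by 0.28. Apoptosis genes had a median of 0.03 (Hrk 0.14, Diablo -0.15) and cytoskeleton and axon growth genes -0.03 (Nefh 0.36, Actb 0.16); Nefh differed by 0.12 without pair 4 and Diablo by -0.01 without pair 1.

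No tested list of markers of the cell types that a tissue punch can hold was called in the main test either. Astrocyte markers came nearest: 8 of 9 were higher, with a median of 0.18 and an SD of 0.20 over the pairs' own list medians. Their camera p was 0.031 before adjustment and 0.968 after it, and the unadjusted p was 0.198 with an estimated correlation. Mt3, a metallothionein of the brain, differed by 0.22 (higher in 5 of 6 pairs) and the intermediate filament gene Vim by 0.18 (3 of 6). With each array feature taken on its own, the astrocyte list passed at an adjusted p of 0.0367 with the preset correlation. On the 7 of its features measured on all arrays, adjusted p was 0.470 with that correlation and 0.884 with an estimated one. Over the other alternatives, the smallest adjusted p of any list lay between 0.149 and 0.995.

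The neuron marker list had a median of 0.02 (Nefh 0.36, Elavl3 0.10) and that of catecholaminergic and cholinergic neurons -0.03, with Slc18a2 at 0.07. Oligodendrocyte and myelin markers had a median of 0.05 (Tspan2 -0.50, Cnp 0.15), microglia and macrophage markers 0.03 (Ctsb 0.10, Tyrobp 0.07) and endothelium and vessel wall markers -0.04 (Tek -0.23, Kdr -0.16). Leaving out 1 pair brought Tspan2 to 0.04, Cnp to 0.01, Tek to -0.04 and Kdr to -0.05. The median was 0.01 for blood cell markers (S100a8 0.27, Pf4 0.10) and 0.13 for choroid plexus, ependyma and leptomeninges (Aqp1 -0.35, Col1a2 0.35); without pair 2, S100a8 differed by -0.12 and Col1a2 by 0.14, and on single features by 0.87 and 1.09. For cerebellum (Cbln1 0.01, Itpr1 0.00) and for Schwann cells and peripheral sensory neurons (Trpv1 -0.15, Calca -0.08), only 2 markers each were measured and no test was made.

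**Figure D2:**
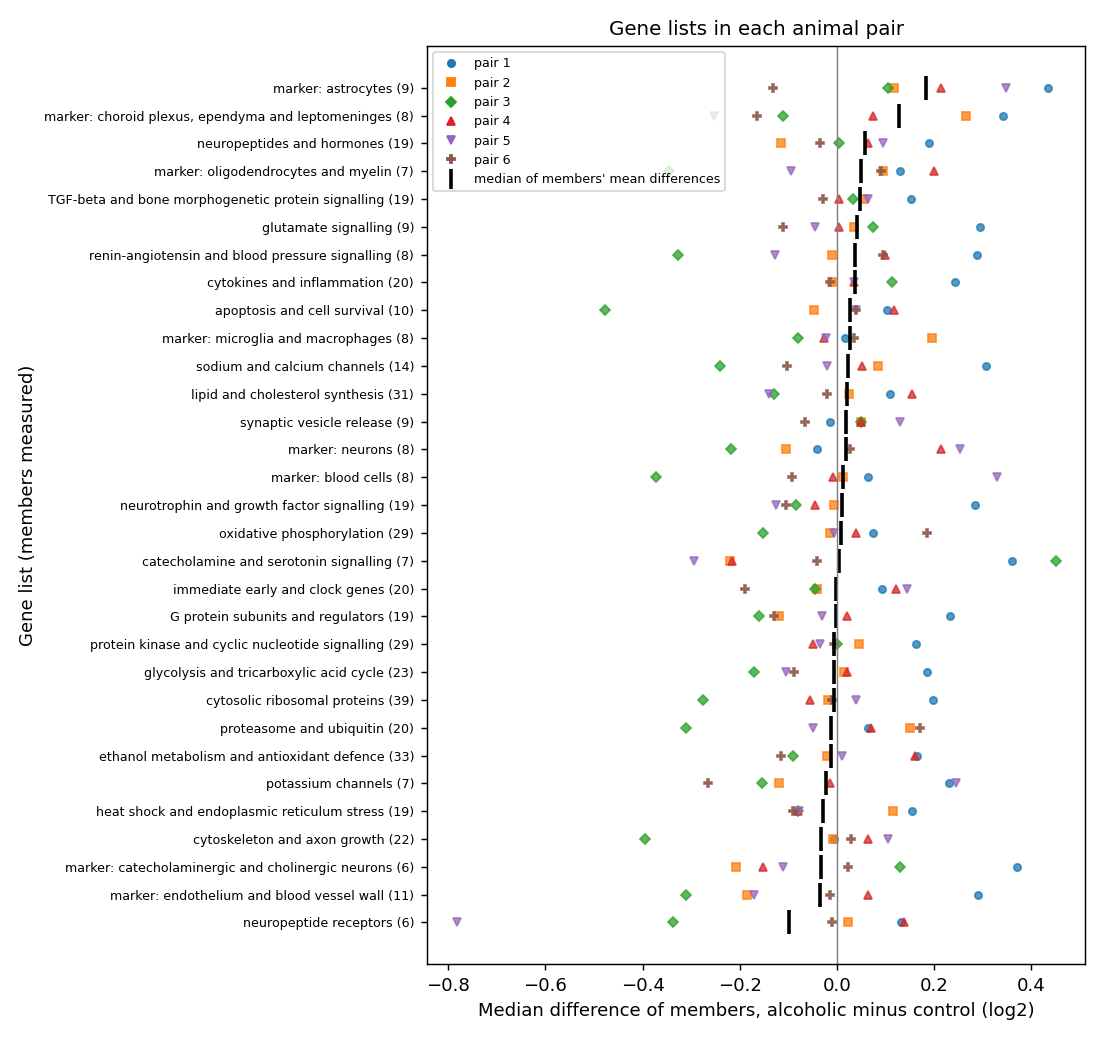
Each point is the median alcoholic minus control difference (x axis, log2) of a list's members in 1 animal pair, for the 31 tested lists on the y axis; upright marks are medians of the members' mean differences. The astrocyte list has the highest median, 0.18, and the points of single pairs lie on both sides of 0 for each list.

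The pairs did not share a common direction. Across the 11011 genes measured in every pair, each pair's differences were correlated with the mean of the other 5 pairs; genes are not independent replicates in these coefficients. The coefficient was 0.09 for pair 4 and -0.19 for pair 3, with a median of -0.07 over the 6 pairs. Pair 3 ran against pair 6 (r = -0.27) and pair 1 (r = -0.21), while pairs 4 and 6 had the highest coefficient, 0.15. The SD of the differences over genes was between 0.51 in pair 4 and 0.65 in pair 6. Among the tested lists, 28 of 31 lay above 0 in pair 1 and 22 in pair 4, and 22 lay below 0 in pair 3 and 22 in pair 6. Named genes as a whole had a median of 0.095 in pair 1 and -0.055 in pair 3, where unnamed features stood at 0.06 and 0.055, so these list counts partly follow the named genes of a pair.

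**Figure D3:**
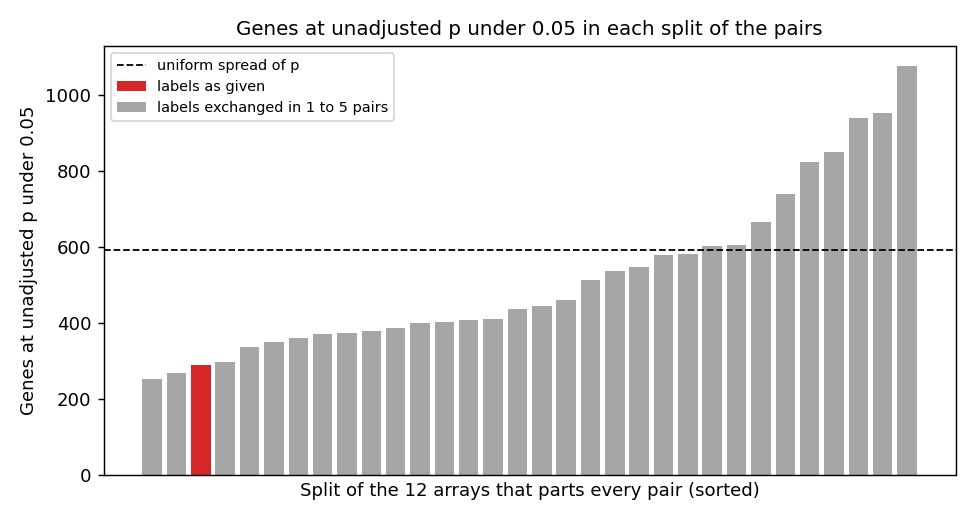
Bars give the number of genes at an unadjusted p under 0.05 (y axis) for each of the 32 ways to assign the group labels within the 6 pairs, sorted along the x axis; the dashed line is the 592 that a uniform spread of p gives. The labels as given gave 290 genes, and the other assignments between 254 and 1076.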

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

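The tests of pair 3, of the astrocyte list and of the differences between pairs were chosen only after the results were seen, as were the counts of label exchanges within pairs. In 13 of 172 groups of arrays tested for the named genes and for 4 measures of the arrays, 1 animal lay far from the others of its group; chance gives about 9. All 13 were values of named genes, 8 in alcoholic and 5 in control animals.

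Among alcoholic animals, Selenos stood at -2.71 in pair 2 against -1.84 to -1.55 in the others, and Cxcr4 at -0.13 in pair 2 against 0.42 to 0.63. Col1a2 was at -2.55 in pair 2, with the others between -3.99 and -3.49. In pair 4, Gabrd was at -1.32, above a range of -1.89 to -1.69, and Nefh at 2.75, above 1.26 to 1.74. Igfbp5 was at 2.34 in pair 1 against at most 0.37 elsewhere, Ifngr1 at 7.68 in pair 5 against at most 4.03, and Tyrobp at 0.83 in pair 3 against at most 0.29. Among control animals, Hspe1 was at -0.62 in pair 3 where the others began at 1.10, Tspan2 at 3.74 in pair 4 where they ended at 0.25, and Tek at 2.29 in pair 6 where they ended at 1.25. Col1a2 was at -4.45 in pair 5, below -3.99, and Calca at -2.16 in pair 6, below -1.40. All these are centred log2 ratios.

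The labels were exchanged within pairs in all 32 ways. The real counts past an adjusted p of 0.05 were 0 genes and 0 lists, which all 32 reach by construction, so that comparison says nothing; the highest of the others was 0 genes and 2 lists. At an unadjusted p under 0.05, 30 of the 32 gave at least the real 290 genes, so chance cannot be excluded, and the highest of the others was 1076, with the labels of pairs 3, 4 and 5 exchanged. The 6 highest counts all came from exchanging pair 3 and not pair 6, which restates as a structure of the samples that pair 3 correlated with pair 6 at -0.27. Without the block, 31 of the 32 gave at least the real 142 genes, so chance cannot be excluded there either, and the highest of the others was 553. All 100 drawn splits of the 12 arrays gave at least 142, with 2724 as the highest of the others. Most of these put pair mates in one group, so differences between animal pairs entered their counts, with a median of 537 where 2 pairs were parted and 360 where 4 were. They are therefore no measure of chance for labels that part every pair, and the 2724 point to a structure of the samples that can be those differences.

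Fewer genes reached an unadjusted p under 0.05 than the 592 of a uniform spread of p, and than the median of 446 over the other label assignments, whose counts with the real one averaged 520.5. Of the 32 assignments, 2 gave fewer genes than the real one, so chance cannot be excluded for the low count. A trend of single arrays with the level of the log2 ratio is argued against as the whole cause, since loess against that level left 327 genes. Exchanging the labels of pair 3 alone gave 740 genes and of pair 6 alone 580, and leaving them out 438 and 361; these counts restate the opposition of the pairs in the same data and test no cause. Whether the 2 labels of pair 3 were exchanged cannot be told apart from animals that differ, since once exchanged the pair correlated above 0.05 with only 2 of the other 5 pairs (0.21 with pair 1 and 0.27 with pair 6). A difference between animals of pair 3 and the others remains open as untested.

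The astrocyte list was the highest of the lists, with S100b at 0.37, Clu at 0.02 and Aldoc at -0.07. Chance among the lists is consistent with it, since 21 of the 32 label assignments gave a smallest list p at least as small as the real 0.031. A lower share of neurons in the alcoholic punches cannot be told apart from a change in astrocyte genes. The neuron list was not lower (0.02), and the astrocyte list exceeded the endothelium list in 5 of 6 pairs, but an exact two-sided sign-flip test of that difference gave p = 0.0625, where 0.03125 is the smallest it can give. An effect of alcohol on astrocyte genes stays open as well.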

How the results depend on the processing

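The loess and exact-zero alternatives, and the estimated correlation on single features, were chosen after seeing the data. The count of genes past an adjusted p of 0.05 stayed at 0 under every alternative but 1. Values without centring, with exact zeros still missing, gave 4. These were Lyl1 (-2.14), Scrt1 (2.43) and 2 features without a single gene, named after their values were seen. In limma's test adjusted p reached 0.0058 there, and over the other alternatives the smallest was 0.0657 to 1.00. The cause was not tested. At unadjusted p under 0.05 the 290 genes became 142 without the pair block and 304 with the pair as a random effect, and the block changed no other call. Leaving out single pairs gave 214 to 438 genes, the latter without pair 3. The list count was 0 except with each feature on its own at the preset correlation, where it was 1. The median coefficient of a pair with the others lay between -0.07 and -0.05. The printed size of single genes is less steady: leaving out 1 pair moved 55 of 82 named genes by over 1.5 times at least once, single features 29 of 77 and exact zeros kept 15 of 82. Of 1587 recomputed values of 82 named genes 1557 kept their direction and side of the threshold, and of 619 list medians 618 did not move beyond their spread. The exception was the synaptic vesicle list, with a median of 0.10 on single features against 0.02 in the main fit. The spread, the SD over the pairs' own list medians, was larger than the size of each tested list's median. A list could therefore change sign and still count as unmoved, so the count says little about how steady the lists are.

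The sign reversed in 28 values of 12 genes, the cause not being tested. With zeros kept, the log2 difference was -0.198 for Scrt1, 0.0083 for Fbxo16 and -0.0025 for Itpr1. Slc32a1 was at 0.049 with single features. Cbln1 was at -0.0425 without centring, -0.0064 after quantile normalization, -0.114 with single features and -0.041 with array weights. Itpr1 was at -0.051 without centring, -0.043 after quantile normalization, -0.037 with a common spread and -0.178 with single features. It was at -0.023 with array weights, -0.012 after loess on the mean ratio and -0.0090 after the further loess. With single pairs left out, the difference ranged from -0.078 to 0.033 for Slc32a1, -0.03 to 0.164 for Elavl3, -0.026 to 0.157 for Slc18a2, -0.809 to 0.041 for Tspan2, -0.055 to 0.136 for Tyrobp and -0.123 to 0.507 for S100a8. The range was -0.117 to 0.110 for Cbln1, -0.082 to 0.064 for Itpr1, -0.195 to 0.086 for Calca and -0.021 to 0.003 for Aldh2. Depth here means signal over background, which was not used.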

Other observations

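The tests of the differences between pairs in this part were chosen only after the results were seen, and the genes named here lie outside the rule for named genes and were picked by the size of their pair effect. Animal pairs differed from each other in single genes, whichever the group. With limma's test of the 5 pair terms, 26 of 11011 genes passed an adjusted p of 0.05, and 2276 (20.7%) had an unadjusted p under 0.05 where chance gives 551. Cldn1, which encodes a tight junction protein, averaged -0.86 and -0.63 in pairs 1 and 2 but -2.94, -2.63, -3.36 and -2.58 in pairs 3 to 6 (adjusted p = 0.0142). St3gal6, a sialyltransferase gene, stood at 0.47 and 0.55 in pairs 1 and 2 and between -1.28 and -0.88 in the others. Zfhx4, Dtwd1 and Srcap likewise stood higher in pairs 1 and 2 than in pairs 3 to 6, while Toe1 and Dut split the pairs in other ways. Shisa4 and Cyp4f4 stood apart in pair 4, at 2.89 and 2.39, with the other pairs at most at 0.21 and 0.06.

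Place in the order of feature numbers is argued against as the whole cause of these pair differences: log F values of features 3 to 12 numbers apart correlated at 0.020 on average. Shuffled orders had an SD of 0.0033 around 0, so a small positional part remained. Differences in the tissue held by the punches cannot be told apart from differences between animals. Nor can either be told apart from any processing step shared by the 2 arrays of a pair, or by the arrays of several pairs. Such steps were not tested. Marker genes had a pair effect 0.95 times as often as other named genes, with a 95% interval from 0.58 to 1.55 over 66 marker genes.

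The median SD over animals was 0.37 in control and 0.32 in alcoholic arrays, with a larger SD in control for 63.1% of genes, a difference that did not pass its test. Exchanging labels within pairs gave as large a difference in 4 of 64 patterns, an exact two-sided p of 0.0625. The median log2 ratio of the SDs, alcoholic over control, was -0.21, and it was -0.13 without pair 6 and -0.32 without pair 2. Duplicate spots had an SD of 0.19 in both groups.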
